A study of Mus musculus with 8 samples.

How the data were processed

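RNA-seq was carried out on left ventricular tissue of 8 FVB mice aged 8 to 12 weeks, 4 homozygous for a deletion of the element RE1 and 4 wild-type littermates. Per the labels' protocols, libraries were made with a stranded total RNA kit from 900 ng of RNA and sequenced as paired-end reads of 125 bases on an Illumina HiSeq 2500. The submitters' processing notes list STAR, a read aligner, DESeq2 and the mouse build mm10, with no versions. The counting program, its strand setting and the annotation release are not given in the sources used here.

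The authors deposited raw read counts per gene for 41128 Ensembl gene IDs, with 1 column per mouse. They also deposited normalized values, a signal on a linear scale. In every library these equal the raw counts divided by a single size factor, with a relative spread of at most 9.86e-15 within a library. A further table deposited by the authors compares the groups with a log2 fold change, a p-value and an adjusted p-value per gene, for which the processing notes name DESeq2 among the tools. The authors' log2 fold change is wild-type over knockout, so its sign was turned for comparisons. Total counts ran from 16778368 to 37133306 per library. Genes with near-identical copies carried near-identical totals in the deposited counts. The total of Rn7s1 differed from that of Rn7s2 by 0.00587%, and that of mt-Co3 from that of its nuclear copy Gm28437 by 0.0709%. Values of genes with near-identical copies are therefore uncertain.

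Gene symbols were taken from the deposited files for 21721 IDs and from GENCODE M21 (build GRCm38, the same assembly as mm10) for 18670. For 91 of the latter the file gave a symbol that belongs to another gene ID in the reference. No symbol was found for 737 IDs. Coordinates are from GENCODE M21. Sequence sharing was measured as the percent of 100-base stretches of a gene's exons that also occur in exons of another gene.

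Raw counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3), with TMM normalization, the filterByExpr filter and group as the only term. P-values are two-sided and Benjamini-Hochberg adjusted over all genes tested, with a threshold of 0.05. Standard errors were derived from the log2 fold change and the F statistic. Means ± SD are of the authors' normalized counts, and log2 CPM values use a prior count of 2. Single values were compared with two-sided exact permutation tests over the 70 assignments of 8 libraries, whose smallest possible p is 0.0286. Counting intervals are at 95% and cover counting error only.

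Before the data were examined, 31 lists of genes for the locus, pathways and cell types were fixed, along with a list of sex-linked genes that was described and not tested. Each list with at least 5 tested genes was compared with all other genes by camera (limma 3.58.1) at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists. Nppa and Nppb were left out of the list tests. Camera with an estimated correlation and fry were run beside it. Counts "adjusted over the list alone" use the edgeR p-values of that list.

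The genes named were set by a rule written at the same time. It takes Nppa and Nppb, the neighbours past the threshold and 6 close neighbours, and the 10 genes with the smallest adjusted p in each direction whose groups did not overlap and whose symbol is not a provisional name. It adds up to 4 members, by smallest p, of each list that was called or held a called gene, and 8 readouts of ventricular stress, matrix and natriuretic peptide receptors. Some genes that the rule takes are not described. Other named genes are marked as chosen after their values were seen.

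The edgeR step was tested on simulated counts for 16551 genes with the means, dispersions and library sizes of these data and 200 changed genes, 50 per fold size. The changed genes were drawn only from genes above a floor of mean count, so these rates do not cover tested genes with lower counts. At 1.25-fold 36% of the changed genes were recovered, at 1.5-fold 76%, at 2-fold 86% and at 4-fold 100%, with 9 false calls among 158. A single planted list at 1.2-fold was called by camera with 0 other lists. The simulated genes were drawn independently of each other, whereas in these data the estimated correlation within a list reached 0.74 (erythroid markers). The simulation therefore does not measure false calls of lists in these data.

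Alternatives were other size factors, other low-count filters, leaving out each library, the replicate number as a block, 1 surrogate variable (sva 3.50.0), DESeq2 1.42.0, limma-voom, limma on the deposited normalized counts, and other thresholds. Covariates for the circadian clock, mitochondrial rRNA and mesothelial markers, and offsets for GC content and transcript length, were added after seeing the data, as was a test on counts drawn once without replacement to the smallest library total. Pairs of libraries of a group differed by more than sampling noise, with a mean chi-square per gene of at least 3.14, so all 8 were counted as separate samples.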

Results

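The series asks how a super enhancer, a dense cluster of regulatory elements, controls the neighbouring genes Nppa and Nppb in the heart. RNA-seq was done on the left ventricle of 4 mice homozygous for a deletion of RE1, an element of this enhancer, and of 4 wild-type littermates. The coordinates of RE1 were not given in the sources used here. Gene counts per library totalled 34742840, 26574894, 20284865 and 24167894 in wild-type replicates 1 to 4 and 16778368, 37133306, 25603006 and 24949413 in RE1 knockout replicates 1 to 4. Mitochondrial rRNA took 8.51% to 10.5% of the counts in wild-type libraries. It took 9.40% and 9.01% in knockout replicates 1 and 3, and 6.40% and 6.19% in knockout replicates 2 and 4. Ddx3y, on the Y chromosome, lay between 86.0 and 102 CPM in all 8 libraries, and Xist, the X-inactivation RNA, between 3.39 and 6.25 CPM.

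Both genes named in the series title were almost lost from the knockout ventricles. Nppb, which encodes B-type natriuretic peptide (ENSMUSG00000029019, chromosome 4, 147985788 to 147987205, GRCm38), was at 2983 ± 1170 normalized counts in wild-type and 6.07 ± 4.37 in knockout ventricles (SD, n = 4 each). Nppa, which encodes atrial natriuretic peptide (ENSMUSG00000041616, chromosome 4, 148000722 to 148002079), was at 419.7 ± 140 normalized counts in wild-type and 6.88 ± 2.26 in knockout ventricles (SD, n = 4 each). The raw counts of Nppb were 1875 to 4266 per wild-type library and 1 to 16 per knockout library. Those of Nppa were 246 to 640 and 4 to 14, so each knockout library matched its label. Nppb fell by 8.82 on the log2 scale (SE 0.58, edgeR adjusted p = 0.00387), which is 451-fold. Nppb was at −9.52 without knockout replicate 2, where its raw count was the highest of the knockout libraries, and at −9.96 and −9.67 with covariates for the clock and for mesothelial markers, both chosen after seeing the data. Nppa fell by 5.84 (SE 0.39, edgeR adjusted p = 0.00169), which is 57.2-fold. On counts pooled over each group, the ratio of wild-type to knockout was 452 for Nppb (counting interval 308 to 692) and 58.1 for Nppa (40.3 to 87.0). The exact permutation test gave p = 0.0286 for each, the smallest the design allows. With a covariate for the circadian clock, chosen after seeing the data, Nppa was at −5.42 with an edgeR adjusted p of 0.15, in a range over the alternatives from 9.46e-45 to 0.15.

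**Figure D1:**
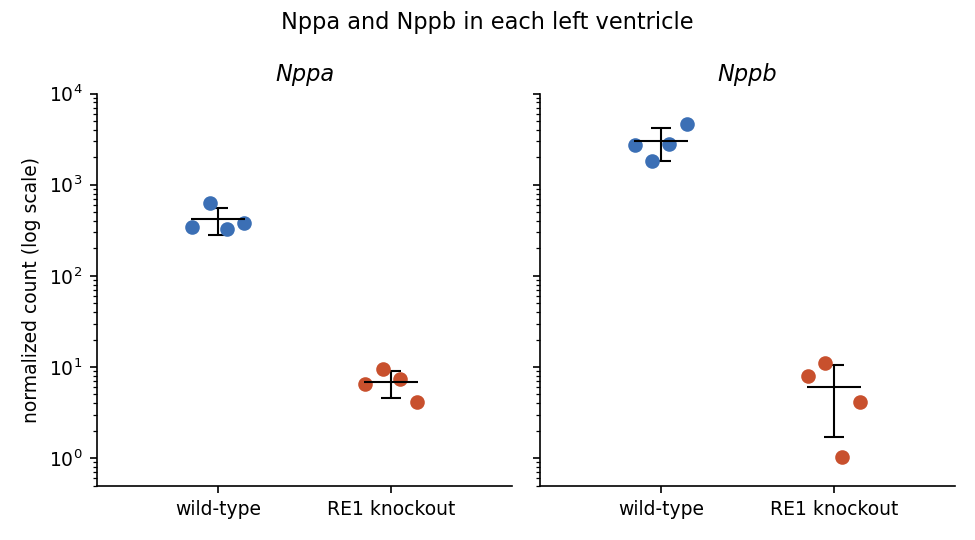
Normalized counts of Nppa (left) and Nppb (right) on a log scale in each of 4 wild-type (blue) and 4 RE1 knockout (orange) left ventricles, with the mean (line) and SD (bars). Knockout means are 6.88 for Nppa and 6.07 for Nppb, against 419.7 and 2983 in wild-type.

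Among the genes around Nppa and Nppb, 3 neighbours also fell, by far smaller amounts. Plod1, a collagen lysyl hydroxylase at 147909753 to 147936767 on chromosome 4, went from 2220 ± 54.4 to 1851 ± 114 normalized counts (SD, n = 4 each), 16.8% lower. The uncharacterised gene 2510039O18Rik, between Plod1 and Nppb at 147940895 to 147947314, was 17.6% lower. Dhrs3, a retinal reductase gene farther off at 144892827 to 144928209, was 20.3% lower. The edgeR adjusted p was 0.0113, 0.0354 and 0.0385, respectively. Of the 40 genes in the list of locus neighbours, 31 were tested. With Nppa and Nppb, 5 fell and 0 rose. Adjusted over the list alone, 6 fell and 0 rose, the added gene being the transcription factor gene Casz1 (log2 fold change −0.16, SE 0.05, edgeR adjusted p = 0.154 over all genes). Of the 29 neighbours other than Nppa and Nppb, 23 had a negative log2 fold change, with a median of −0.09. Camera called these 29 lower (adjusted p = 0.00438; adjusted p = 0.192 with an estimated correlation), and fry gave an adjusted p of 0.00356.

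Other genes close to Nppa and Nppb did not pass the test. Clcn6, a chloride transporter gene whose end lies beside Nppa, had a log2 fold change of −0.17 (SE 0.08, edgeR adjusted p = 0.389). Agtrap was at −0.10 (SE 0.06), Miip at −0.13 (SE 0.11) and Mfn2, a gene of mitochondrial fusion, at −0.03 (SE 0.05), each with an edgeR adjusted p of at least 0.524. Farther out, 3 zinc-finger genes singled out after their values were seen were higher: Gm13212 by 1.45-fold, Gm13251 by 1.22-fold and Gm13139 by 1.21-fold (edgeR adjusted p 0.00686, 0.0198 and 0.0385). They share 27.4%, 28.6% and 70.3% of their 100-base stretches with other genes, so their counts are uncertain. The number of list members past the threshold was 2 without wild-type replicate 1 or knockout replicate 2, and 3 without wild-type replicate 3, knockout replicate 1 or knockout replicate 3. It was 1 with the clock covariate and 2 with a covariate for mitochondrial rRNA or for mesothelial markers. The call of Plod1 ended without wild-type replicate 1 or knockout replicate 2, that of Dhrs3 in 6 of the 8 fits without a library, and that of 2510039O18Rik in 7. Of the zinc-finger genes, Gm13212 kept its call in all 8 such fits, Gm13251 in 6 and Gm13139 in 1.

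**Figure D2:**
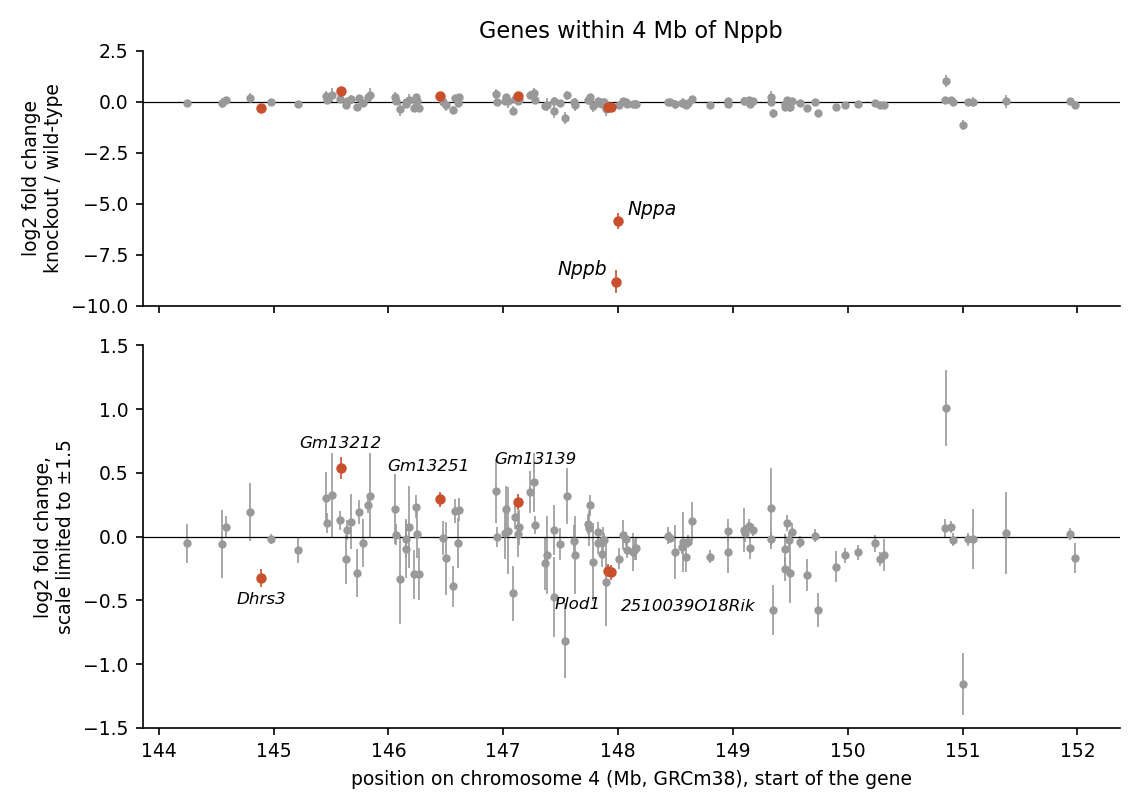
Log2 fold change (knockout over wild-type, bars are SE) of each tested gene whose start lies within 4 Mb of Nppb on chromosome 4, on the full scale (top) and a scale limited to ±1.5 (bottom), with genes past an edgeR adjusted p of 0.05 in orange. Nppb and Nppa lie at −8.82 and −5.84, and the other orange genes between −0.33 and 0.54.

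Across the genome, 62 genes were higher and 114 lower in the knockout out of 16551 tested. Apart from Nppa and Nppb, the changes were small: the median absolute log2 fold change of the other 174 genes was 0.37, or 1.30-fold, and 15 of them reached a log2 fold change of 1 in size. The groups did not overlap in log2 CPM for 165 of the 176 genes. Over all genes tested this held for 7.15%, against 2.86% by chance. The counts of higher and lower genes were 16 and 34 without wild-type replicate 1, 30 and 52 without knockout replicate 1, 8 and 28 without knockout replicate 2, and 36 and 68 without knockout replicate 3. They were 52 and 72 without wild-type replicate 2 and 108 and 151 without wild-type replicate 4, while DESeq2 called 110 and 196, limma on the deposited normalized counts 37 and 65, and edgeR without the low-count filter 269 and 374. A clock index, the mean log2 CPM of 4 genes of the Arntl arm minus that of 8 genes of the Dbp and Per arm, ran from −3.17 to −1.16 in wild-type and from −0.76 to 0.32 in knockout libraries. With this index as a covariate, chosen after seeing the data, edgeR called 0 genes higher and 1 lower, with 1276 at an unadjusted p under 0.05. It called 36 and 52 with the share of mitochondrial rRNA, and 0 and 10 with an index of mesothelial markers (1460 at an unadjusted p under 0.05).

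The 10 higher genes with the smallest adjusted p differed by far less than Nppa and Nppb. Among them Mmp14, a membrane-bound matrix metalloproteinase, rose from 191 ± 32.1 to 318 ± 9.79 normalized counts (SD, n = 4 each; log2 fold change 0.73, SE 0.10, edgeR adjusted p = 0.00169). The metalloproteinase gene Adamts15 rose 1.59-fold and Eln, which encodes elastin, 1.37-fold. Gsn, which encodes the actin-severing protein gelsolin, was far more abundant and rose from 21380 ± 840 to 25690 ± 1185 normalized counts (SD, n = 4 each), 20.1% higher. Also among the 10 were Rhoj (1.49-fold), the phosphatase gene Ptpn13 (1.55-fold), the muscarinic receptor gene Chrm2 (1.19-fold), the transcription factor gene Cebpd (1.59-fold) and Ush1c (1.78-fold). The edgeR adjusted p of these 9 genes ran from 0.00169 to 0.0113. Chrm2 and Cebpd overlap genes on the opposite strand. Without knockout replicate 2, the calls of Eln, Chrm2, Cebpd and Ush1c ended, with edgeR adjusted p from 0.0577 to 0.0703.

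Of the 10 lower genes, Nppa is given above and the other 9 differed by 1.28-fold to 1.65-fold. The transcription factor gene Hic1 fell from 394 ± 41.9 to 240 ± 7.44 normalized counts (SD, n = 4 each; log2 fold change −0.72, SE 0.08, edgeR adjusted p = 0.00127). Nrp2, a co-receptor for vascular endothelial growth factors and semaphorins, was 1.30-fold lower. The transcription factor gene Sox7 was 37.6% lower, the adhesion molecule gene Icam2 1.39-fold lower and the chemokine gene Cxcl12 1.28-fold lower. The phosphatase gene Ptp4a3 was 1.31-fold lower, the lysophospholipase gene Pnpla7 1.33-fold lower and the clock gene Nr1d1 1.42-fold lower. Gvin1, an interferon-inducible GTPase gene, was 1.32-fold lower, but it shares 97.8% of its 100-base stretches with other genes, mainly Gm4070. The edgeR adjusted p of these 10 genes ran from 0.00127 to 0.00387, and each call held when any single library was left out. Nrp2 and Nr1d1 overlap genes on the opposite strand, Nr1d1 the gene Thra. The strand setting of the counts is not given in the sources used here, so the counts of such genes are uncertain. Among the other genes named this also holds for Mfn2, Gm13139, Gm13251, Cry2, Tspan4, Dbp, Gata6, Herpud1, Jun, mt-Nd5, mt-Nd6, Actc1, Uqcrb, Myh7 and Corin. The groups of every named gene past the threshold lay apart in log2 CPM except those of Gbp2. For the 10 higher and the 10 lower genes this was a condition of their choice.

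Genes of the circadian clock differed in opposite directions. Npas2, a paralogue of Clock, rose 2.98-fold from 23.5 ± 14.3 to 67.3 ± 14.2 normalized counts (SD, n = 4 each; log2 fold change 1.58, SE 0.30, edgeR adjusted p = 0.0246). The repressor Cry2 fell 1.62-fold from 614 ± 89.1 to 382 ± 36.1 (log2 fold change −0.70, SE 0.10, edgeR adjusted p = 0.00606). Of the 21 clock genes tested, 3 rose (Npas2 and Nfil3 among them), 5 fell (Nr1d1, Cry2, Tspan4, Rora and Nr1d2) and 13 did not pass. Nfil3, Rora and Nr1d2 were singled out after their values were seen, as were Arntl and Dbp, and the calls of Nfil3, Rora and Nr1d2 ended in 5 to 7 of the 8 fits without a library. Adjusted over the list alone, 5 rose and 13 fell. Arntl, the partner of Clock, had a log2 fold change of 1.81 (SE 0.52, edgeR adjusted p = 0.231) and Dbp, an output gene, of −1.82 (SE 0.37, edgeR adjusted p = 0.110). Camera called the list lower (adjusted p = 1.08e-04; adjusted p = 0.275 with an estimated correlation). The clock index, built after these values were seen, differed between the groups by 2.23. The call of Tspan4 ended without wild-type replicate 2 or knockout replicate 1, 2 or 3. That of Npas2 ended without wild-type replicate 1 or 3 or knockout replicate 2, 3 or 4, with edgeR adjusted p of up to 0.112.

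**Figure D3:**
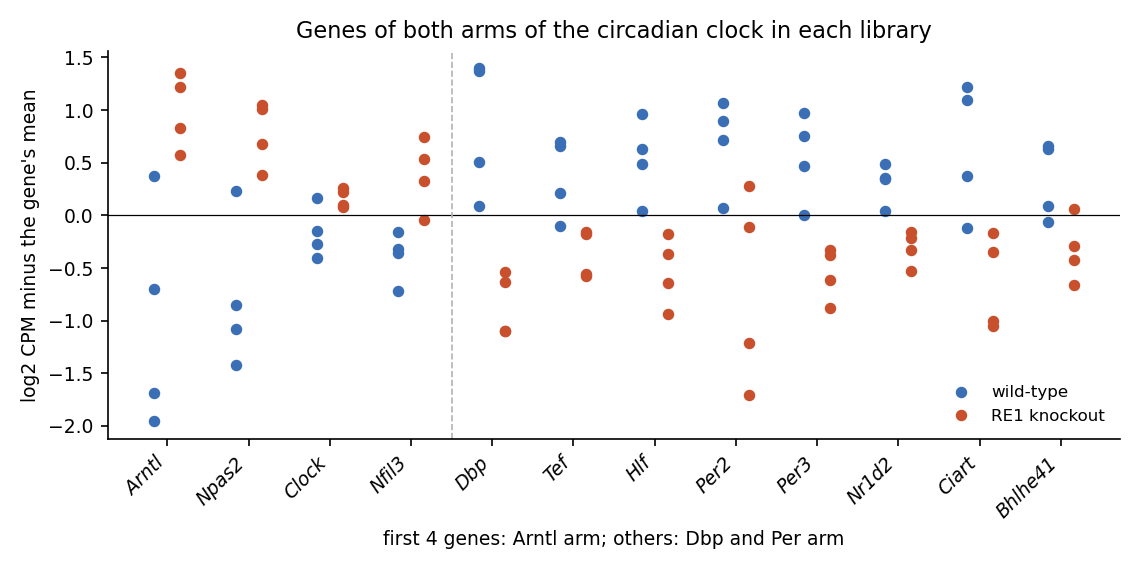
Log2 CPM of 12 clock genes in each library, with the mean of the gene over all 8 libraries taken off, for wild-type (blue) and RE1 knockout (orange). For Npas2 the groups lie apart (log2 fold change 1.58), as they do for Dbp in the other direction (−1.82), and single libraries of a group also differ from each other.

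The list of endothelial markers was called lower by camera and fry, but not by camera with an estimated correlation (adjusted p = 0.192). Of 22 tested, 20 were negative, 4 fell, 0 rose and 18 did not pass, and 7 fell adjusted over the list alone. The largest change in the list went the other way, Cldn5 at 0.80 (SE 0.33, edgeR adjusted p = 0.384). The other positive gene was Tek at 0.003 (SE 0.05). Both were named after their values were seen. Cav1, which encodes the main protein of caveolae, went from 4286 ± 273 to 3442 ± 239 normalized counts (SD, n = 4 each; log2 fold change −0.32, SE 0.05, edgeR adjusted p = 0.0099). Robo4, the transcription factor gene Erg and Ly6c1 were 19.1%, 19.3% and 17.6% lower (edgeR adjusted p 0.0318, 0.0415 and 0.0415). The list had a median log2 fold change of −0.13 (camera adjusted p = 1.52e-05, fry adjusted p = 0.0271). The call of Cav1 held when any single library was left out, whereas those of Robo4, Erg and Ly6c1 each ended in 6 of 8 such fits, wild-type replicate 1 and knockout replicates 1, 2 and 3 among them. Endocardial markers were also called lower, with a median of −0.15 over 10 genes (adjusted p = 0.0261; adjusted p = 0.462 with an estimated correlation). None of the 10 passed over all genes, and 3 fell adjusted over the list alone: Nfatc1 (−0.27, SE 0.08), Smoc1 (−0.91, SE 0.28) and Cgnl1 (−0.17, SE 0.06), with edgeR adjusted p over all genes of 0.0988, 0.140 and 0.205. The call ended without wild-type replicate 1 or 4 or knockout replicate 2.

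The lists of fibroblast markers and of matrix genes were called higher by camera, but not with an estimated correlation (adjusted p 0.462 and 0.511). Of 20 fibroblast markers, 2 rose, Gsn and Pdgfra, the receptor gene for platelet-derived growth factor A (1.33-fold, from 1181 ± 98.1 to 1575 ± 156 normalized counts, SD, n = 4 each, edgeR adjusted p = 0.013). The call of Pdgfra ended without knockout replicate 2 (edgeR adjusted p = 0.0597). None fell, and 5 rose adjusted over the list alone. Of 43 collagen and matrix genes, 29 were positive and 14 negative. Of these 2 rose, Mmp14 and Eln, 41 did not pass, and adjusted over the list alone 7 rose and 3 fell. Loxl1 and Fbln2, both of elastic fibres, had log2 fold changes of 0.28 (SE 0.07) and 0.22 (SE 0.06), with edgeR adjusted p of 0.056 and 0.0789. The main fibrillar collagen gene Col1a1 (0.19, SE 0.23, edgeR adjusted p = 0.793) and Postn, a gene of activated fibroblasts (−0.11, SE 0.12, edgeR adjusted p = 0.762), did not pass. The lists had medians of 0.07 and 0.12 (camera adjusted p 0.0261 and 0.00898). Both calls ended without wild-type replicate 3 or knockout replicate 3, and that of the fibroblast markers also without wild-type replicate 4 or knockout replicate 4.

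Mesothelial and epicardial markers, genes of the heart's outer lining, were called higher as a list by camera, but not with an estimated correlation (adjusted p = 0.332), and the groups overlapped. All 12 tested had a positive log2 fold change with a median of 1.43, none passed over all genes, and 1 rose adjusted over the list alone (the keratin gene Krt18, log2 fold change 1.17, SE 0.32, edgeR adjusted p = 0.0923 over all genes). Bnc1 had a log2 fold change of 2.03 (SE 0.67, edgeR adjusted p = 0.225). The camera adjusted p was 7.68e-07, and the median was 2.60 without wild-type replicate 4 and 2.05 without knockout replicate 4. The mean log2 CPM of Upk3b, Msln, Bnc1 and Lrrn4 was −1.11, −2.05, −1.01 and 0.88 in wild-type and 1.81, 1.95, 0.98 and −0.33 in knockout replicates 1 to 4. Erythroid markers were called higher as well, with a median of 0.20 over 10 genes and none past the threshold (adjusted p = 0.0122; adjusted p = 0.511 with an estimated correlation). The β-globin gene Hbb-bt, which shares 54.8% of its stretches with Hbb-bs, was at 0.25 (SE 0.20, edgeR adjusted p = 0.661). That call ended without wild-type replicate 1 or knockout replicate 1 or 3.

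Genes of the cardiomyocyte differed by small amounts and mostly did not pass singly. Of 26 calcium-handling genes 1 rose, Casq2, which encodes the calcium buffer of the sarcoplasmic reticulum (1.15-fold, edgeR adjusted p = 0.0493; its call ended in 7 of 8 fits without a library), and 4 rose and 1 fell adjusted over the list alone. The list had a median of 0.05 and was called higher (camera adjusted p = 0.00941; adjusted p = 0.462 with an estimated correlation), but not without knockout replicate 1. Among 22 adult contractile genes none passed over all genes, 18 were positive with a median of 0.07, and adjusted over the list alone 2 rose and 1 fell. Myoz2 was at 0.16 (SE 0.05), Actc1 at 0.19 (SE 0.06) and Tcap, a titin-capping protein gene, at −0.54 (SE 0.11), with edgeR adjusted p of 0.0988, 0.148 and 0.0761. The list was called higher (camera adjusted p = 0.0242; adjusted p = 0.511 with an estimated correlation), but not without wild-type replicate 1 or 2 or knockout replicate 1, 3 or 4. Of 53 nuclear genes of oxidative phosphorylation 50 were positive with a median of 0.07 and none passed over all genes, 1 rising adjusted over the list alone (Uqcrb, 0.16, SE 0.04, edgeR adjusted p = 0.0643). Camera called this list higher (adjusted p = 2.34e-06; adjusted p = 0.462 with an estimated correlation). The 15 mitochondrially encoded genes were called lower with a median of −0.14 and none past the threshold (adjusted p = 0.008; adjusted p = 0.511 with an estimated correlation). mt-Nd5 was at −0.29 (SE 0.11, edgeR adjusted p = 0.321), and this call ended without wild-type replicate 3 or knockout replicate 2 or 4. The score of this list was −0.24 and −0.23 in knockout replicates 2 and 4, where mitochondrial rRNA took 6.40% and 6.19% of the counts. In knockout replicates 1 and 3 it was 0.05 and 0.07, inside the wild-type range of −0.03 to 0.15.

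In the edgeR fit, ventricular stress genes showed no single change past the threshold. The β-myosin gene Myh7, a marker of the fetal programme that shares 7.71% of its stretches with Myh6, was at 0.01 (SE 0.04), Ankrd1 at 0.06 (SE 0.08) and the skeletal actin gene Acta1 at 0.64 (SE 0.43), with edgeR adjusted p of 0.980, 0.788 and 0.610. Acta1 was at 21460 normalized counts in wild-type replicate 2 and at 7346 to 7589 in the other wild-type libraries. It was at 13940 to 22350 in the knockout libraries, so the groups overlapped only through wild-type replicate 2. The list of 26 hypertrophy and fetal genes had a median of 0.10 and was called higher (camera adjusted p = 0.0242; adjusted p = 0.511 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. Rcan1, a calcineurin inhibitor gene, was at 0.64 (SE 0.18, edgeR adjusted p = 0.223), but the authors' deposited table gave it an adjusted p of 0.0203. The call ended without wild-type replicate 2 or knockout replicate 1 or 3. Natriuretic peptide and cGMP signalling was not called (19 genes without Nppa and Nppb, median 0.03, camera adjusted p = 0.529), and 2 of its genes fell adjusted over the list alone. These were Corin, the protease that activates atrial natriuretic peptide (−0.15, SE 0.05, edgeR adjusted p = 0.140), and Pcsk6, a protease gene named after its values were seen (−0.16, SE 0.05, edgeR adjusted p = 0.148). The receptor genes Npr1 (0.14, SE 0.07) and Npr3 (0.04, SE 0.12) had edgeR adjusted p of 0.445 and 0.939.

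Genes of excitation and of cardiac transcription moved singly in both directions. Among 30 potassium and sodium channel genes and connexins Gja1, which encodes connexin 43, rose 1.26-fold from 8771 ± 827 to 11020 ± 832 normalized counts, and Kcnj2, an inward rectifier channel gene, fell 16.7% from 1335 ± 35.3 to 1107 ± 106 (SD, n = 4 each; edgeR adjusted p 0.0399 and 0.0415). Their calls ended in 5 and 6 of the 8 fits without a library. The list was not called (median −0.04, camera adjusted p = 0.0694). Conduction system markers were called lower with a median of −0.16 over 15 genes and none past the threshold, Cntn2 being at −0.88 (SE 0.35, edgeR adjusted p = 0.349). This call (camera adjusted p = 0.0421; adjusted p = 0.462 with an estimated correlation) ended without wild-type replicate 2 or 4 or knockout replicate 1, 3 or 4. Of 26 cardiac transcription factors Gata6 rose 1.28-fold and Mef2d fell 1.16-fold (edgeR adjusted p 0.0204 and 0.0385), calls that ended in 3 and 7 of the 8 fits without a library, and the list was not called (median 0.04, camera adjusted p = 0.660).

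Camera called the lists of interferon-response and cell-cycle genes lower and that of immediate early genes higher, but none of these calls held with an estimated correlation (adjusted p 0.264, 0.264 and 0.275). Of 28 interferon genes 27 were negative with a median of −0.33, and 3 fell: Ifit3 by 2.25-fold, I830012O16Rik by 2.11-fold and Gbp2 by 1.36-fold (edgeR adjusted p 0.0453, 0.0332 and 0.0438). I830012O16Rik, named Ifit3b in the reference, and Ifit3 share 27.4% and 31.6% of their stretches with other genes, mainly each other, so their separate counts are uncertain. The calls of Ifit3, I830012O16Rik and Gbp2 ended in 7, 6 and 7 of the 8 fits without a library. Adjusted over the list alone 6 fell (camera adjusted p = 4.72e-08). Of 29 cell-cycle genes 26 were negative with a median of −0.37, and 1 fell, the replication helicase gene Mcm6 (1.81-fold, from 90.6 ± 25.3 to 49.5 ± 9.27 normalized counts, SD, n = 4 each, edgeR adjusted p = 0.0415; its call ended in 6 of the 8 such fits). Top2a was at −0.90 (SE 0.22, edgeR adjusted p = 0.0829), and 2 fell adjusted over the list alone (camera adjusted p = 2.34e-06). Of 25 immediate early genes 21 were positive with a median of 0.39, and 1 rose, Klf6 (1.24-fold, edgeR adjusted p = 0.0197), whose call ended without wild-type replicate 1 or knockout replicate 1 or 2. Jun was at 0.54 (SE 0.11, edgeR adjusted p = 0.0626). Adjusted over the list alone, 8 rose and 1 fell (camera adjusted p = 3.37e-06). These 3 list calls held when any single library was left out, as did those of the locus neighbours, endothelial, mesothelial, circadian and nuclear oxidative phosphorylation lists.

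**Figure D4:**
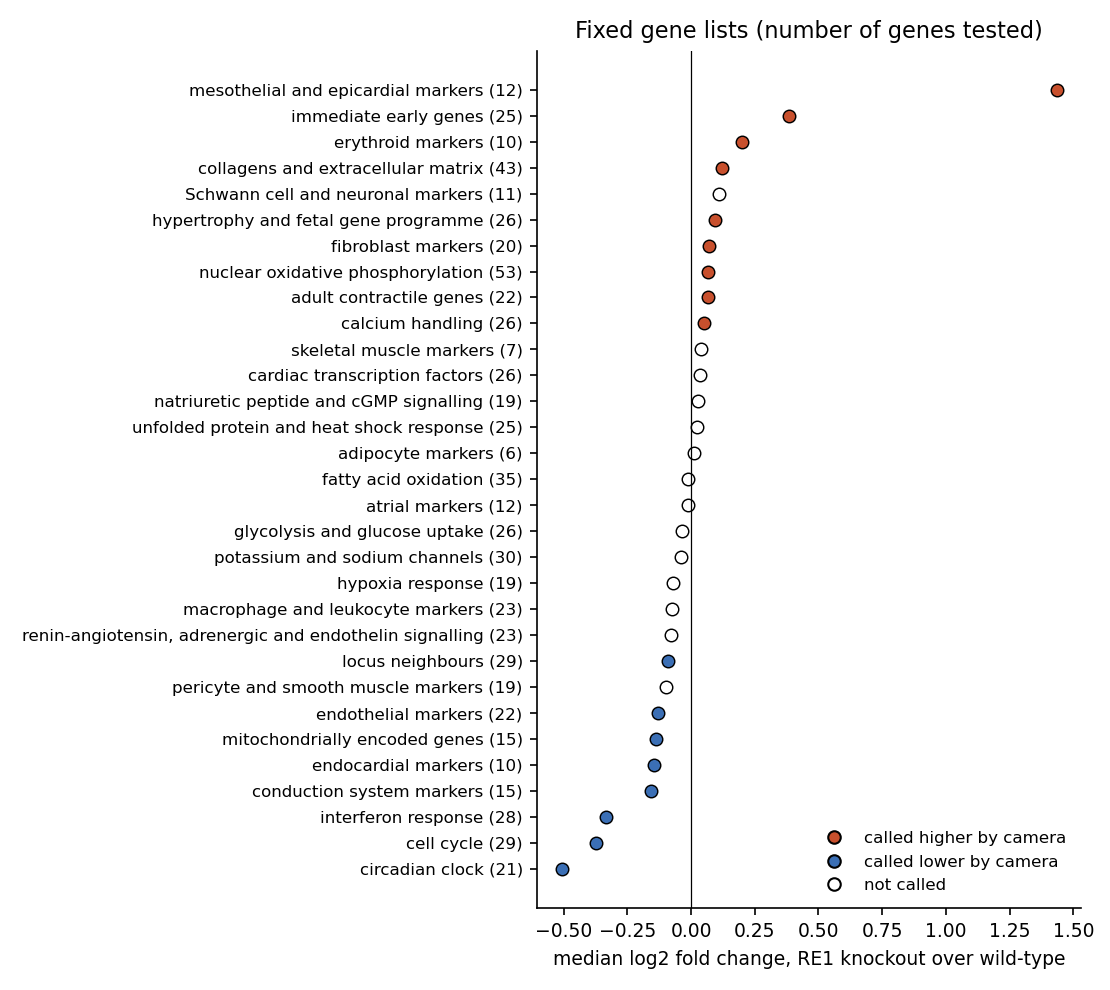
Median log2 fold change (knockout over wild-type) of each of 31 fixed gene lists, with the number of genes tested in brackets; orange and blue points are lists called higher or lower by camera with a preset correlation, white points are not called. Mesothelial and epicardial markers stand highest at 1.43 and circadian clock genes lowest at −0.51, and none of the 17 calls held with an estimated correlation.

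Camera called 9 lists higher and 8 lower of the 31 tested, 11 in all without knockout replicate 3, 5 with the clock covariate and 8 with that for mesothelial markers. With an estimated correlation it called 0 (4 at an unadjusted p under 0.05), and fry called 2, locus neighbours and endothelial markers. In lists that were not called, the hypoxia response held 1 gene that rose, Ddit4, an inhibitor of mTOR signalling (2.31-fold, from 166 ± 23.3 to 392 ± 103 normalized counts, SD, n = 4 each, edgeR adjusted p = 0.023; list median −0.07, camera adjusted p = 0.137), a call that ended in 5 of the 8 fits without a library. The unfolded protein and heat shock response held 1 that fell, Herpud1 (16.4% lower, edgeR adjusted p = 0.023; list median 0.02 and camera direction lower, adjusted p = 0.880), whose call ended without wild-type replicate 1 or knockout replicate 2 or 4. Apart from these and the lists of channels and transcription factors above, the lists not called held no gene past the threshold. Medians were −0.01 for fatty acid oxidation, −0.04 for glycolysis and glucose uptake, −0.10 for pericytes and smooth muscle, and −0.07 for macrophages and leukocytes. They were 0.11 for Schwann cells and neurons, 0.04 for skeletal muscle, and −0.08 for renin-angiotensin, adrenergic and endothelin signalling. Atrial markers other than Nppa had a median of −0.01 and a mean of 0.03, with the camera direction lower, and adipocyte markers a median of 0.01 and a mean of −0.16, with the camera direction higher. Camera adjusted p of these 9 lists ran from 0.118 to 0.785.

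The authors' deposited table gave nearly the same fold changes. Across the 16551 genes in both, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.999 and a Spearman correlation of 0.999. The authors' deposited table had 86 genes higher and 155 lower in the knockout at an adjusted p under 0.05, among 14259 genes with an adjusted p. Of the edgeR calls, 50 higher and 98 lower genes were shared with it, 0 had opposite directions and 28 were not called there. Some genes described above as not past the edgeR threshold were called in the authors' table. Among them were Tcap (adjusted p there 1.02e-06), Dbp (5.00e-06), Jun (5.66e-04), Rcan1 (0.0203), Uqcrb (0.0205) and Loxl1 (0.0456). Whether these genes passed thus depended on the test used. The authors' deposited table gives Nppb a log2 fold change of 8.91 and Nppa of 5.88, wild-type over knockout, with adjusted p of 3.21e-60 for both.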

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

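The splits for the gene counts and the tests of both readings of the clock genes, of sequence shared between paralogs, of a linked strain variant and of the cardiomyocyte share were chosen after the result was seen. So were the clock and mesothelial indices, the simulations of the slope test, its bound at 50% of a full effect and the thinning to equal depth.

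Of the 35 ways to split the 8 libraries into groups of 4, only the real one (1 of 35) gave as many genes past the threshold, 176 against at most 17 in another split. The same held for gene lists (1 of 35, 17 against at most 12) and for genes of the locus (1 of 35, 5 against at most 0). A share of 1 of 35 (0.0286) is the smallest that these splits allow, so it argues against chance at 0.05 but does not exclude it. Splits that mix the groups hold the difference between the groups inside each group, which can lower their counts. The 5 genes of the locus include Nppa and Nppb, and up to 12 lists passed camera in splits that mix the groups.

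The first pattern is the shift of the clock genes, with small changes in many genes outside the locus; the clock index differed by 2.23 between the groups, and its widest span within a group was 90.3% of that, so a different phase of the clock at sampling is a candidate explanation for the clock genes. An effect of the RE1 deletion on the clock cannot be told apart from it, since the labels of 0 of the 8 libraries give a time of sampling. For the 166 calls outside the natriuretic peptide and clock genes, 54.8% stayed past the threshold after every library was thinned to 16778368 counts (median log2 fold change 0.36 before and 0.37 after in size, median SE 0.07 and 0.08) and 78.9% with offsets for GC content and transcript length, which argues against depth and against these as the whole cause. Slopes within groups on the share of mitochondrial rRNA gave −2.21% of the summed change (SD 4.24), which with 2 SD added is 6.27%. The 166 top genes of a simulated full effect reached 34.1% (SD 15.9), and 50% of that is 17.1%. That simulation gave only 1 gene past the threshold, so its top genes are unlike the 166 calls. With so wide an SD as well, the test cannot decide whether mitochondrial rRNA gave 50% or more of the change. For clock phase the share was 19.7% (SD 12.2), and it cannot be told apart from an effect of the deletion. The reason is that 5 called clock genes outside the index reached only 30.7% (SD 19.3) in the same test (a simulated full effect 64.6%). On that value 50% of a full effect would give 15.4%, and with an SD that wide it may give less.

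The second pattern is the calls near Nppa and Nppb, where 4.88% of 123 genes within 4 Mb passed, against 1.02% elsewhere. Dhrs3, Plod1 and 2510039O18Rik share 0% of their 100-base stretches with other genes, which argues against reads shared between paralogs for these 3. The higher zinc-finger genes Gm13212, Gm13251 and Gm13139 share at least 27.4%, so for them shared reads remain a candidate explanation. A linked strain variant carried along with the deletion cannot be told apart from an effect of the deletion, since the deposited tables hold no reads from which to read a haplotype; calls were denser there (Fisher's exact p = 0.00191), but not past 0.05 without the 3 zinc-finger genes (p = 0.128). Clock phase gave −12.8% of the summed change (SD 12.3), which with 2 SD added is 11.9% and under the 15.4% for 50% of a full effect. That bound rests on 5 called clock genes, whose share of 30.7% had an SD of 19.3. The test therefore cannot decide whether clock phase gave 50% or more of the change. All 6 calls ended with the clock covariate. Under it Plod1 was at −0.23, 2510039O18Rik at −0.25, Dhrs3 at −0.43, Gm13139 at 0.32, Gm13251 at 0.33 and Gm13212 at 0.66. Errors widened under it, the median SE of the 174 calls other than Nppa and Nppb being 0.07 without and 0.14 with it.

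The third pattern is the endothelial list called lower with the fibroblast, matrix and mesothelial lists called higher, calls by camera that ended with an estimated correlation. A lower share of cardiomyocytes would raise markers of all other cell types alike. The score of the endothelial list, fixed before the data were examined, was lower in the knockout, with a difference of −0.136 (fry adjusted p = 0.0271 over the 31 lists). This argues against a lower share of cardiomyocytes as the sole cause of the pattern. It is not an independent test, since the lower endothelial list is part of the pattern to be explained. Epicardial tissue in the sample gave 4.45% of the summed change of the 8 called endothelial, fibroblast and matrix genes (SD 9.24), and it cannot be told apart from an effect of the deletion, since a simulated full effect reached only 35.3% and 50% of that, 17.7%, lies within 2 SD. Clock phase, at 9.10% (SD 16.9), cannot be told apart either, since the 15.4% for 50% of a full effect lies within 1 SD. A change in the endothelial or fibroblast cells of knockout ventricles also remains open, as untested.

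Within each group of 4, the named genes, list scores, indices and library totals were searched for a library far from the other 3 by Dixon's ratio at its 95% critical value. Of 316 groups 16 passed, and chance gives about 15.8. In wild-type libraries the log2 CPM of Rhoj was 4.08 in replicate 4 against 3.63 to 3.70 in the others, that of Ptp4a3 was 6.56 in replicate 2 against 6.74 to 6.77, and that of Cacna2d1 was 7.13 in replicate 3 against 6.94 to 6.96. Scn4a was at 4.98 in replicate 1 against 5.34 to 5.37, Herpud1 at 7.05 in replicate 1 against 6.87 to 6.89, and Top2a at 1.99 in replicate 4 against 2.58 to 2.67. Acta1 was at 9.67 in replicate 2 against 8.12 to 8.17, and Postn at 5.22 in replicate 2 against 4.78 to 4.84. In knockout libraries Gvin1 was at 6.33 in replicate 1 against 6.41 to 6.43, Loxl1 at 4.54 in replicate 1 against 4.44 to 4.45, and Fbln2 at 6.73 in replicate 2 against 6.56 to 6.57. Nfatc1 was at 3.34 in replicate 3 against 3.46 to 3.48, and Socs3 at 1.62 in replicate 4 against 1.89 to 1.95. Among scores of lists, that of locus neighbours was 0.054 in wild-type replicate 2 against 0.038 to 0.039 in the others, that of hypertrophy and fetal genes was 0.0082 in wild-type replicate 4 against −0.10 to −0.084, and that of the hypoxia response was −0.041 in wild-type replicate 3 against 0.054 to 0.072.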

How the results depend on the processing

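The covariates for the clock index, the share of mitochondrial rRNA and the mesothelial index and the offsets for GC content and length were chosen after the data were seen. Nppb kept its direction and its call in every fit that gave it a value, with an adjusted p from 9.46e-52 to 0.0290, and Nppa in all but the clock fit, from 9.46e-45 to 0.15. All 176 called genes kept their direction in every fit in which they were tested. Of 1008 values of named genes past the threshold in other fits 713 stayed past it, 295 did not and 0 reversed. Of 1508 values of named genes not past it 94 came past it and 28 reversed, and of 558 values of lists 487 stayed on their side. Without 1 library, 8 to 108 genes were higher and 28 to 151 lower, 2 to 4 genes of the locus and 11 to 15 lists passed, and Nppa ranged from −6.12 to −5.57 and Nppb from −9.52 to −8.48. With the replicate number as a block, which did not pair the libraries, 70 genes were higher and 116 lower, and 137 of the 176 calls were kept. A Y-linked covariate was not run, since all 8 libraries expressed these genes.

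Higher and lower genes numbered 269 and 374 without the low-count filter, 110 and 196 by DESeq2, 37 and 65 by limma on the deposited normalized counts, 8 and 23 at an adjusted p under 0.01, and 128 and 218 under 0.10. Against a fold of 1.2 glmTreat called 0 and 3, with 459 at an unadjusted p under 0.05. The clock covariate left 0 and 1 (1276 at an unadjusted p under 0.05), 1 gene of the locus and 5 lists, with Nppa at −5.42 and an adjusted p of 0.15. Under it the median absolute log2 fold change of the 174 calls other than Nppa and Nppb went from 0.37 to 0.29 and their median SE from 0.07 to 0.14. Changes were thus smaller and errors wider, and which of these ended a call was not tested. The clock index itself had a correlation of 0.855 with group. With the share of mitochondrial rRNA 36 and 52 genes passed, 45 of them among the 176, and 2 of the locus. Over the 174 calls the median was 0.38 and the median SE 0.10. With the mesothelial index 0 and 10 passed (1460 at an unadjusted p under 0.05), 7 of them among the 176, along with 2 of the locus and 8 lists. Here the median over the 174 calls was 0.34 and the median SE 0.10. Camera with an estimated correlation called 0 lists (4 at an unadjusted p under 0.05) and fry 2. The correlation with the authors' fold changes was 0.9989 by Spearman and 0.953 without the filter.

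Values that reversed were not past the threshold for any gene, and the cause was not tested. Without 1 library, Myh7 ranged from −0.015 to 0.026, Postn from −0.21 to 0.0067, Npr3 from −0.063 to 0.10 and Mfn2 from −0.069 to 0.012. With 1 surrogate variable Myh7 was at −0.00088. With the clock covariate Mfn2 was at 0.0099, Mybpc2 at −0.17, mt-Nd4 at 0.024, mt-Nd5 at 0.12, mt-Nd6 at 0.19, mt-Nd4l at 0.13, Bnc1 at −0.0045, Efemp1 at −0.17, Cyr61 at −0.016, Hmox1 at 0.17, Myh7 at −0.042, Npr1 at −0.0057, Arntl at −0.10 and the list of mitochondrially encoded genes at 0.12. With the mitochondrial rRNA share Mfn2 was at 0.10 and the list of mitochondrially encoded genes at 0.0090. In that fit the camera direction of the unfolded protein response went from lower to higher, while its median was positive both without the covariate (0.02) and with it (0.12). With the mesothelial index Myh7 was at −0.037, Col1a1 at −0.028 and Npr3 at −0.051, and with GC and length offsets Mfn2 was at 0.00088. Without the low-count filter the list of adipocyte markers was at −1.12. At this depth and number of libraries, 76% of simulated changes of 1.5-fold were found and 36% of the smallest ones planted, so many changes of that size were not detectable. The changes were planted only in genes above a floor of mean count, so these rates do not cover genes with lower counts.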

Other observations

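The clock index was chosen after the data were seen. The libraries of each group were not alike. Knockout replicates 1 and 3 differed from each other by a mean chi-square per gene of 3.14, and replicates 2 and 4 by 3.61, against 14.5 to 16.5 for the other pairs of knockout libraries. Pairs of wild-type libraries differed by 4.98 to 13.1. The clock index was −0.76 and −0.68 in knockout replicates 1 and 3 and 0.30 and 0.32 in replicates 2 and 4, and the score of mitochondrially encoded genes was 0.05 and 0.07 against −0.24 and −0.23.

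Genes on the Y chromosome were at like levels in the libraries except for Kdm5d, a histone demethylase gene, which was at 12.2 CPM in knockout replicate 3 and at 21.1 to 24.7 CPM in the others. All genes with symbols starting with Rn7s, Rn7s1 and Rn7s2 among them, together took 11.3% to 13.6% of the counts of a library. The totals of Rn7s1 and Rn7s2 were near-identical, so this share is uncertain.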
